A study of Mus musculus with 42 samples.

How the data were processed

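RNA sequencing of mouse brain tissue was deposited for 42 samples of 6 regions: lateral habenula (LHb), ventral hippocampus (vHippo), ventral tegmental area (VTA), nucleus accumbens (NAc), medial prefrontal cortex (mPFC) and lateral hypothalamus (LH). Mice had gone through chronic restraint stress (CRS) or were naive, and all were tested in the forced swim test (FST) 2 days before sacrifice. The samples formed 14 groups of 3 libraries. LHb libraries were divided by stress and by FST immobility into naive low FST (below 50 s), naive high FST (50 to 80 s), CRS low FST (50 to 110 s) and CRS high FST (above 110 s). The labels gave no FST class for the other regions, where CRS and naive groups were compared. The labels do not state that replicates are separate animals, nor whether libraries of different regions come from the same mice.

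The deposited tables hold whole-number read counts per gene and FPKM per gene (fragments scaled by transcript length and library size), per the file headers. Per the submitters' processing notes, reads were handled with cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, and edgeR is named without a version. How the counts were taken, and whether strand was used, is not stated, so overlapping and antisense genes cannot be told apart here. The FPKM values were normalised by the authors per library. LHb libraries were in a table of 37410 genes, and the 5 other regions in a second table of 40905 genes, of which 1800 had a summed count of 0. Each of the 12 and 30 FPKM columns correlated best with the count column of its own library. A further 18 columns of counts matched no sample and were not used here.

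The notes name GRCm39. Gene starts in the LHb table equalled those of GENCODE M21 (GRCm38) for 2.181% of the 34900 genes matched by ID. In the table of the 5 other regions 99.519% of starts were equal over 40748 matched genes, so those coordinates are GRCm38, while the notes name another build. Coordinates are given only for LHb genes, as the table gives them. Gene symbols, IDs and Gene Ontology (GO) terms came from the tables, and GO terms were not used for 2519 genes of the LHb table and 2253 of the other.

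Total counts per library ran from 56459734 to 79849567 in LHb and from 53143878 to 81384893 in the other regions. Mitochondrial genes took 5.25% to 7.43% of counts in LHb and 5.22% to 14.7% elsewhere, and ribosomal RNA took 0.219% to 3.60% and 0.101% to 7.00%. Each library had 25992 to 28026 genes with a count in LHb and 24399 to 27145 elsewhere. No pair of libraries within a group was a copy of another: over 42 pairs, chi-square per degree of freedom for equal expected counts ran from 24.1 to 427.

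The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a single gene is from this test unless another tool is named. The 12 LHb libraries went into a single fit with 4 group means, and 23266 genes were tested. Each other region was fitted alone on 6 libraries, with 20224 genes in vHippo, 20124 in VTA, 20275 in NAc, 20064 in mPFC and 20206 in LH. An F test of the CRS effect by region used the 30 libraries of the 5 regions and 24244 genes. Log2 fold changes have standard errors (SE) from the fit, and FPKM values are means with the standard deviation (SD) over libraries.

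Among genes past the threshold with a symbol that is not a predicted or clone name and a mean FPKM of at least 1, the 5 with the largest log2 fold change and the 5 with the smallest p were named per direction, or all where fewer than 5 passed. Where none passed, the 3 of smallest p per direction were named. A set of 16 focus genes of autophagy, glutamate receptors and the stress response was named whatever the result, with up to 4 members of smallest p of each list described. Region identity was given by up to 3 members of each region's marker list with the highest mean.

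Gene lists (36, each with at least 5 tested members) were tested with camera in limma 3.58.1, on log2 of library-scaled counts with a prior count of 2, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. GO terms with 10 to 500 members among the tested genes were tested with a one-sided Fisher's exact test where at least 20 genes passed in a direction.

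The fits were tested on simulated data, made from the means and library sizes of the real libraries with 200 genes changed, 50 at each fold of 1.5, 2, 3 and 4. The list test recovered a list planted at a fold of 1.2 with each of the 3 methods, and called 0 other lists. Simulated genes were drawn independently of each other. The absence of other calls therefore says nothing about false calls where genes of a list vary together, as in real libraries.

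Alternatives were DESeq2 1.42.0, edgeR with median-ratio (RLE) factors, limma on log2(FPKM + 1), on log2(FPKM + 0.1) and after median-ratio scaling, no filter, a filter of at least 5 FPKM in 3 libraries, the replicate number of the labels as a block, 2 groups or all libraries in a fit, and leaving out each library in turn. Chosen after the data were seen were an offset for transcript length and GC content, fits without the naive low FST libraries, without libraries holding choroid plexus RNA or pancreas RNA, and without ribosomal and mitochondrial genes, and contrasts of other LHb groups with the naive low FST group. Short lists of transcripts of other tissues were also written after the data were seen. Analysis of levels and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and the R package data.table was at version 1.17.8.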

Results

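RNA was measured in tissue of 6 mouse brain regions after chronic restraint stress (CRS), a repeated immobilisation used to model depression, and in naive mice. In the lateral habenula (LHb) 12 libraries formed 4 groups of 3: naive mice with low (below 50 s) or high (50 to 80 s) immobility in the forced swim test (FST), and CRS mice with low (50 to 110 s) or high (above 110 s) immobility. Ventral hippocampus (vHippo), ventral tegmental area (VTA), nucleus accumbens (NAc), medial prefrontal cortex (mPFC) and lateral hypothalamus (LH) each had 3 naive and 3 CRS libraries. Total counts ran from 56459734 to 79849567 per LHb library and from 53143878 to 81384893 per library of the other regions.

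Most of the region markers named here had their highest mean in their own region, at levels that varied between libraries. Gpr151, an orphan receptor gene of habenular neurons, was at 199 ± 24.2 FPKM (SD, n = 12) in LHb and at means of 0.322 to 0.681 FPKM elsewhere. Scube1 was at 79.3 ± 9.72 FPKM in LHb, while Gap43, also on the lateral habenula list, was lower in LHb (77.2 FPKM) than in the other 5 regions (99.0 to 240). Tac2, Calb2 and Lrrc55, listed as markers of the neighbouring medial habenula, were at 159 ± 25.8, 275 ± 26.5 and 166 ± 15.8 FPKM in LHb. In vHippo, Cpne7 was at 113 ± 40.5 FPKM and Neurod6, a transcription factor gene of pyramidal neurons, at 70.7 ± 8.08 FPKM (SD, n = 6). The dopamine transporter gene Slc6a3 was at 176 ± 197 FPKM in VTA, with single libraries from 1.63 to 552, and Th, of dopamine synthesis, ran from 12.4 to 420. Penk and Ppp1r1b, of striatal projection neurons, were at 445 ± 151 and 289 ± 93.4 FPKM in NAc, where Slc17a7, a vesicular glutamate transporter gene of cortical neurons, ran from 0.507 to 180. Slc17a7 was at 203 ± 45.5 FPKM in mPFC, and Mef2c at 51.1 ± 18.3. Pmch and Hcrt, the precursors of melanin-concentrating hormone and orexin, were at 772 ± 447 and 322 ± 164 FPKM in LH.

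The first comparison asked what CRS changed in LHb, over both FST classes. Shc3 (ENSMUSG00000021448, chromosome 13, 51585077 to 51723523), an adaptor of receptor tyrosine kinases in neurons, was at 6.90 ± 0.658 FPKM in CRS and 3.78 ± 3.27 in naive libraries (SD, n = 6 each). Its log2 fold change was 1.54 ± 0.09 (SE; adjusted p = 1.1e-05). Log2 fold changes of this comparison average the FST classes on the log scale, so they need not match the ratio of mean FPKM. The potassium channel gene Kcna3 (ENSMUSG00000047959, chromosome 3, 106943485 to 106945386) rose by 2.03 ± 0.33 (adjusted p = 0.0102). Hipk2, a nuclear kinase gene (chromosome 6, 38671325 to 38853099), rose by 1.40 ± 0.10 (adjusted p = 0.000145), and Acvr2b, an activin receptor gene (chromosome 9, 119231184 to 119264061), by 1.2005 ± 0.10 (adjusted p = 0.000342). The wide spread in naive mice came from the FST classes: Shc3 was at 0.787 to 0.861 FPKM in the 3 naive low FST libraries and at 5.73 to 7.55 in the other 9.

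Also among the genes higher in CRS than in naive LHb were Ghrl, the ghrelin precursor (2.00 ± 0.32, adjusted p = 0.00999), and Slc9a7, a sodium-proton exchanger of the Golgi (1.76 ± 0.29, adjusted p = 0.0126). Oprm1, the mu-opioid receptor, rose by 1.58 ± 0.33 (adjusted p = 0.0380). Klhl11 (1.68 ± 0.35, adjusted p = 0.0417), Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase (0.77 ± 0.07, adjusted p = 0.000435), and Faxc (0.85 ± 0.08, adjusted p = 0.000735) rose too. Without the naive low FST libraries, an alternative chosen after the data were seen, 0 genes passed (2018 at an unadjusted p below 0.05), and the log2 fold changes of Shc3, Acvr2b, Ghrl, Slc9a7, Klhl11 and Oprm1 turned negative, from −0.191 to −0.00342. Mrps25, of the mitochondrial ribosome, was lower in each CRS library than in any naive library, at 5.16 ± 0.321 against 7.89 ± 1.96 FPKM (log2 fold change −0.59 ± 0.07, adjusted p = 0.00244). Amd1, of polyamine synthesis, was at −0.27 ± 0.05 (adjusted p = 0.0200). Pcdha12, which shares exons with its cluster (−0.55 ± 0.11), Rnf8, a ubiquitin ligase of the DNA damage response (−0.47 ± 0.10), Ahsa2 (−0.34 ± 0.06) and the splicing kinase Clk4 (−0.34 ± 0.06) fell as well, with adjusted p from 0.0208 to 0.0447. In all, 273 genes passed in edgeR, 258 higher and 15 lower, and 0 GO terms were enriched among the higher ones.

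**Figure D1:**
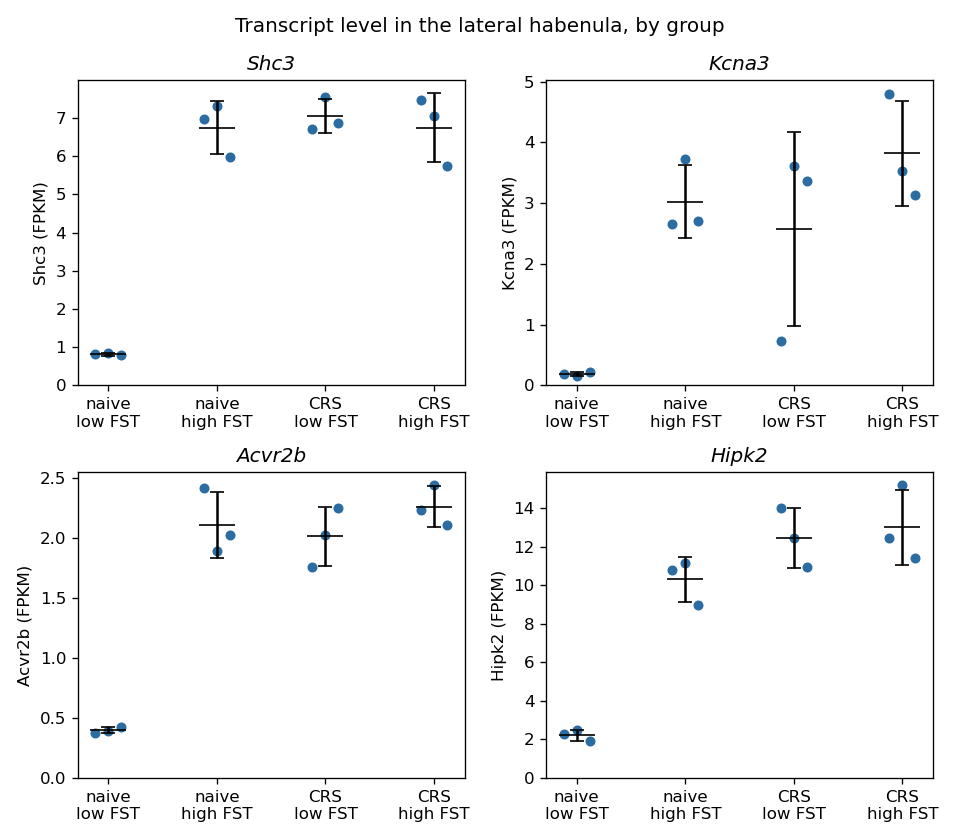
FPKM of Shc3, Kcna3, Acvr2b and Hipk2 in each of the 12 LHb libraries (points) by stress and FST class, with the mean and SD of each group of 3 (black). The naive low FST libraries sat below all others for Shc3, at 0.787 to 0.861 FPKM against 5.73 to 7.55.

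Autophagy, the process named in the series title, was followed with its own lists in LHb. Of the 16 focus genes 0 passed between CRS and naive LHb, 2 had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone. Map1lc3b, the LC3B gene, was at −0.077 ± 0.05 (adjusted p = 0.544), and Sqstm1, the p62 cargo receptor, at −0.030 ± 0.05 (adjusted p = 0.850). Becn1 was at −0.082 ± 0.04 (adjusted p = 0.469), Atg5 at −0.14 ± 0.08 (adjusted p = 0.538) and Atg7 at −0.040 ± 0.08 (adjusted p = 0.875). Log2 fold changes of the regulators Ulk1, Tfeb, Mtor and Prkaa2 were 0.080, 0.095, 0.16 and 0.16, with adjusted p from 0.337 to 0.803, and Lamp1 was at −0.060 (adjusted p = 0.692). The glutamate receptor genes Gria1, Gria2 and Grin2b were at 0.0074, 0.012 and 0.28 (adjusted p from 0.399 to 0.977), and the stress response genes Fkbp5, Sgk1 and Fos at −0.090, 0.44 and 0.45 (adjusted p from 0.334 to 0.720).

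A few members of the autophagy and mTOR lists outside that set passed as higher. Atg2b, which moves lipid to the growing autophagosome, was at 5.86 ± 0.369 FPKM in CRS and 4.19 ± 0.983 in naive LHb (log2 fold change 0.50 ± 0.06, adjusted p = 0.00231). Wdfy3, a scaffold for aggregate clearance, rose by 0.49 ± 0.06 (adjusted p = 0.00346) and Epg5, of autophagosome-lysosome fusion, by 0.37 ± 0.08 (adjusted p = 0.0496). Sesn3, a sestrin gene on the mTOR and AMPK list, rose by 0.38 ± 0.08 (adjusted p = 0.0325). As lists, autophagosome formation (39 genes, 1 higher, and 1 adjusted over the list alone) had a median of −0.051 and an adjusted p of 0.105 in camera. For receptors and fusion (34 genes, 2 higher, and 2 adjusted over the list alone) it was 0.629, and for mTOR and AMPK signalling (49 genes, 1 higher, and 2 adjusted over the list alone) 0.929. Across the other LHb comparisons the adjusted p of formation ran from 0.175 to 0.757, and in the other regions from 0.0979 to 0.982. Atg2b, Wdfy3 and Epg5 also differed between the naive FST classes, as given with that comparison. Both comparisons use the same naive low FST libraries, so the second is not separate evidence. Without those libraries, a fit chosen after the data were seen, 0 of the 21 named genes called between CRS and naive LHb kept their call.

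Camera called 8 of the 36 lists between CRS and naive LHb, 2 higher and 6 lower, and none of them with an estimated correlation (adjusted p = 0.680 or more). All 61 genes of oxidative phosphorylation had a negative log2 fold change (median −0.15, adjusted p = 5.7e-14). Cox7b was lowest in p at −0.39 ± 0.09 (adjusted p = 0.0781), and 0 of them passed, over all genes tested or adjusted over the list alone. The 31 proteasome genes were negative too (median −0.10, adjusted p = 7.8e-07), as were 22 of 26 chaperones (median −0.11, adjusted p = 1.2e-05) and 21 of 25 myelin genes (median −0.11, adjusted p = 0.000579). Lower by their medians were the pan-neuronal genes (median −0.11, adjusted p = 0.00772) and 32 of 50 lysosome genes (median −0.045, adjusted p = 0.0133). Immediate early genes were positive in 24 of 33 (median 0.25, adjusted p = 0.000615), with Fosb at 0.85 ± 0.22 (adjusted p = 0.108) and Atf3 at 0.999 ± 0.28 (adjusted p = 0.149). Leptomeningeal genes were positive in 17 of 18 (median 0.39, adjusted p = 0.00957). The count of 273 genes was 2 without the 4 libraries that held pancreas transcripts, which leaves 1 CRS high library, and 147 with an offset for transcript length and GC content, both chosen after the data were seen.

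Naive mice of the 2 FST classes asked which LHb transcripts went with immobility without stress, and differed in more genes than CRS and naive mice did. Kcna3 was at 3.03 ± 0.608 FPKM in high and 0.187 ± 0.0371 in low FST mice (SD, n = 3 each; log2 fold change 4.05 ± 0.51, adjusted p = 0.00145). Slc9a7 was at 8.09 ± 0.453 against 0.648 ± 0.00413 (3.68 ± 0.45, adjusted p = 0.00138) and Oprm1 at 1.87 ± 0.190 against 0.197 ± 0.0567 (3.27 ± 0.49, adjusted p = 0.00375). Shc3 rose by 3.08 ± 0.13 (adjusted p = 3.7e-07), and Acvr2b by 2.42 ± 0.15 (adjusted p = 1.8e-05). Hipk2 rose by 2.25 ± 0.15 (adjusted p = 1.8e-05), Faxc by 1.64 ± 0.12 (adjusted p = 2.6e-05) and Pdpr by 1.48 ± 0.10 (adjusted p = 1.8e-05). Each of these 8 genes was higher in 3 of 3 libraries than in any low FST library. Klhl11 (3.75 ± 0.54, adjusted p = 0.00310) and Rn18s-rs5, of the multi-copy ribosomal RNA genes (3.24 ± 0.65, adjusted p = 0.0187), rose as well. Kdr, the endothelial VEGF receptor, was lower in high FST mice, at 1.44 ± 0.386 against 3.45 ± 1.16 FPKM (−1.23 ± 0.25, adjusted p = 0.0204). Mmrn2, also endothelial, was at −1.21 ± 0.27 (adjusted p = 0.0334), and Aldh1a2, of retinoic acid synthesis in meninges, at −1.97 ± 0.48 (adjusted p = 0.0479). Aldh1a2 varied between the low FST libraries (4.24 ± 3.26 FPKM), as did Itih2 (2.31 ± 1.61 FPKM), and naive low 1 held choroid plexus RNA, with Ttr at 6834 FPKM. Itih2 (−1.79 ± 0.41), Zc3h11a, which overlaps another gene (−1.29 ± 0.23), and the glial transcription factor Nfia (−0.88 ± 0.12) fell too. So did the mitochondrial tRNA mt-Tm (−0.80 ± 0.14), Mrps25 (−0.58 ± 0.10), Igfbp5 (−0.54 ± 0.09) and Hexim1 (−0.34 ± 0.06), and the adjusted p of these 7 ran from 0.00276 to 0.0369.

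Of the list of potassium, HCN and T-type calcium channels, Kcna1 rose between naive FST classes by 1.52 ± 0.13 (adjusted p = 9.4e-05), Kcnma1 by 0.73 ± 0.16 (adjusted p = 0.0256) and Kcna2 by 0.65 ± 0.13 (adjusted p = 0.0183). Of autophagy and mTOR genes, Pdpk1 rose by 0.64 ± 0.10 (adjusted p = 0.00353), and Atg2b by 0.63 ± 0.08 (adjusted p = 0.00189). Epg5 rose by 0.56 ± 0.11 (adjusted p = 0.0187), Wdfy3 by 0.51 ± 0.09 (adjusted p = 0.00817) and Sesn3 by 0.48 ± 0.11 (adjusted p = 0.0350). Eif4ebp2, a repressor of translation, fell by 0.36 ± 0.08 (adjusted p = 0.0224). Both autophagy lists were not called (adjusted p = 0.757 and 0.715). Of the 16 focus genes 0 passed, 4 had an unadjusted p below 0.05, and 2 passed adjusted over the list alone, the glutamate receptor genes Grin2b (0.66, adjusted p = 0.0828 over all genes) and Gria2 (0.58, adjusted p = 0.0971).

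Camera called 13 lists between naive FST classes, 4 higher and 9 lower, and none of them with an estimated correlation (adjusted p = 0.691 or more). All 24 endothelial genes were negative (median −0.63, adjusted p = 1.5e-11), and 5 passed, or 16 adjusted over the list alone, among them Cdh5 (−1.19 ± 0.25), Slco1a4 (−0.84 ± 0.16) and the pericyte gene Rgs5 (−0.79 ± 0.16). Leptomeningeal genes had a median of −1.95 (adjusted p = 9.3e-06, 14 lower adjusted over the list alone) and the 21 choroid plexus and ependymal genes of −2.86 (adjusted p = 0.00011). The choroid plexus transcript Ttr was at 6834, 2797 and 4389 FPKM in naive low 1, CRS high 1 and CRS low 1 and at 95.3 FPKM or less in the other LHb libraries. The 13 genes encoded by mitochondrial DNA were all negative (median −0.28, adjusted p = 2.3e-05, 5 lower adjusted over the list alone). So were 38 of 50 lysosome genes (median −0.14, adjusted p = 0.0003), with Tpp1 at −0.43 ± 0.10 (adjusted p = 0.0384). Chaperones (−0.11, adjusted p = 0.01), astrocyte (−0.14, 0.0127), microglia (−0.16, 0.0168, with Csf1r at −0.43 ± 0.09) and unfolded protein response genes (−0.13, 0.0298) were lower by their medians. Immediate early genes (0.22, adjusted p = 0.00536), red blood cell genes (0.31, 0.0321), oxidative phosphorylation (0.10, 0.0321) and the potassium, HCN and T-type calcium channels (0.070, 0.0351) were higher.

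In edgeR 715 genes passed between naive FST classes, 625 higher and 90 lower, and the lower ones were 275 of 1041 with the replicate block and 407 of 1673 in DESeq2. GO terms enriched among the higher genes were guanyl-nucleotide exchange factor activity (16 of 170 genes), axon (18 of 232), chromatin organization (16 of 186) and ventricular septum development (5 of 14), each with an adjusted p of 0.0185 in a one-sided Fisher's exact test. Also enriched were protein kinase A binding (5 of 18, adjusted p = 0.0337) and regulation of multicellular organism growth (4 of 11, adjusted p = 0.0487), while 0 terms passed among the lower genes. The GO test did not allow for transcript length. Genes higher in the other LHb groups than in naive low FST mice had a median transcript of 6375 nt, against 2722 nt in genes not called. Enrichment of these terms thus cannot be told apart from a difference in transcript length. Pancreas transcripts were at 358 to 472 FPKM in sum in naive high 3, CRS high 2, CRS high 3 and CRS low 2, and at 0.503 or less in the other 8 LHb libraries. Without those 4 libraries 138 genes passed between naive FST classes.

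CRS high FST mice were compared with naive low FST mice, the groups farthest apart in immobility. The naive low FST libraries were also the control between naive classes. Kcna3 was at 3.82 ± 0.865 against 0.187 ± 0.0371 FPKM (SD, n = 3 each; log2 fold change 4.35 ± 0.51, adjusted p = 0.000662) and Shc3 at 6.75 ± 0.903 against 0.821 ± 0.0376 (3.05 ± 0.13, adjusted p = 4.1e-07). Hipk2 was at 13.0 ± 1.95 against 2.23 ± 0.289 (2.57 ± 0.15, adjusted p = 1.1e-05). Aff2, an X-linked gene, was at 3.97 ± 0.949 against 0.451 ± 0.0781 (3.15 ± 0.26, adjusted p = 9.3e-05). Slc9a7 (3.80 ± 0.45), Klhl11 (3.79 ± 0.54), Oprm1 (3.39 ± 0.49), Acvr2b (2.50 ± 0.15), Faxc (1.74 ± 0.12) and Pdpr (1.52 ± 0.10) rose as well, with adjusted p from 1.1e-05 to 0.00236. Mrps25 fell from 9.59 ± 0.889 to 4.99 ± 0.347 FPKM (−0.92 ± 0.10, adjusted p = 0.000403). Rad52, of homologous recombination (−0.94 ± 0.18), Fam229b (−0.94 ± 0.19), Zc3h11a (−0.94 ± 0.23), C78859 (−0.88 ± 0.17), Ahsa2 (−0.54 ± 0.09), Clk4 (−0.53 ± 0.09), Amd1 (−0.41 ± 0.07) and Rab9b (−0.40 ± 0.07) fell, with adjusted p from 0.00415 to 0.0453.

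Of autophagy and mTOR genes, Atg2b rose by 0.85 ± 0.08 (adjusted p = 0.000212) between CRS high and naive low FST mice, and Wdfy3 by 0.74 ± 0.09 (adjusted p = 0.000700). Sesn3 rose by 0.69 ± 0.11 (adjusted p = 0.00363), and Pdpk1 by 0.64 ± 0.10 (adjusted p = 0.00267). Epg5 rose by 0.63 ± 0.11 (adjusted p = 0.00813) and Rictor by 0.56 ± 0.13 (adjusted p = 0.0337), and Eif4ebp2 fell by 0.31 ± 0.08 (adjusted p = 0.0404). Both autophagy lists were not called (adjusted p = 0.427 and 0.907), and of the 16 focus genes 0 passed, 5 had an unadjusted p below 0.05, and 0 passed adjusted over the list alone. Camera called 8 lists, and none of them with an estimated correlation (adjusted p = 0.921 or more). Endothelial genes were lower (median −0.49, adjusted p = 6.6e-07, 1 lower and 8 adjusted over the list alone), and so were chaperones (median −0.17, adjusted p = 1.1e-05), with Hsph1 at −0.26 ± 0.06 and Dnajb5 at −0.29 ± 0.07. Negative in 48 of 50 were lysosome genes (median −0.14, adjusted p = 2.6e-05), in 30 of 31 proteasome genes (−0.11, 0.000247) and in 13 of 13 genes encoded by mitochondrial DNA (−0.21, 0.00104). Oxidative phosphorylation (−0.10, 0.0013) and myelin (−0.15, 0.00511) were lower and immediate early genes higher (0.21, 0.00598). In edgeR 854 genes passed, 773 higher and 81 lower, 942 passed with the replicate block, and 57 without the 4 libraries that held pancreas transcripts, which leaves 1 CRS high library, assumed to vary like the other groups. Enriched GO terms among the higher genes were chromatin organization, exchange factor activity (adjusted p = 0.0374) and ventricular septum development (adjusted p = 0.0408), and among the lower genes miRNA-mediated gene silencing (adjusted p = 0.0396), in a one-sided Fisher's exact test. Here too the GO test did not allow for transcript length, so terms of the higher genes cannot be told apart from a difference in length.

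Between CRS mice of high and low FST class, which asked what went with immobility after stress, no gene passed. The genes of smallest p were Gnpnat1, of hexosamine synthesis, at 3.30 against 1.26 FPKM (log2 fold change 1.38 ± 0.33), the matrix gene Tnc (0.66 ± 0.16) and Ikzf5 (0.34 ± 0.09). Next were the microglial Fc receptor gene Fcgr3 (−0.70 ± 0.18), Rad52 (−0.61 ± 0.18) and Akip1 (−0.71 ± 0.21), and none of the 6 passed. Camera called 5 lists, and none of them with an estimated correlation (adjusted p = 0.924 or more). Of endothelial genes 22 of 24 were negative (median −0.24, adjusted p = 4.3e-05), with leptomeningeal genes at a median of −0.86 (adjusted p = 0.000707). Immediate early genes (25 of 33 negative, median −0.23, adjusted p = 0.00762), thalamic neuron markers (−0.15, 0.00762) and glucocorticoid response genes (−0.11, 0.0341) were lower too. In edgeR 0 genes passed (494 at an unadjusted p below 0.05), 2 in DESeq2 and 0 in limma, and of the 16 focus genes 0 had an unadjusted p below 0.05.

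CRS low FST and naive high FST mice, whose immobility ranges lie closest across stress, also had no gene past the threshold. St6gal1, a sialyltransferase gene, was at 6.15 against 4.38 FPKM (log2 fold change 0.46 ± 0.10), and Foxk1, a repressor of autophagy genes in muscle, at 0.34 ± 0.08. Pcdhga2, which shares exons with its cluster (0.60 ± 0.12), and the multi-copy Rn18s-rs5 (−3.14 ± 0.65) and Rn7s2 (−3.66 ± 0.79) were also among those of smallest p, each with adjusted p = 0.644. Camera called 13 lists. Of oxidative phosphorylation genes 57 of 61 were negative (median −0.20, adjusted p = 1.9e-14; adjusted p = 0.578 with an estimated correlation). Lower by their medians were pan-neuronal (−0.16, 3.8e-05), ribosomal protein (−0.10, 0.00615), proteasome (−0.082, 0.0026) and red blood cell genes (−2.43, 0.00131). Choroid plexus (2.31, 3.3e-07), leptomeningeal (1.64, 7.1e-11), endothelial (0.40, 5.9e-09), immediate early (0.25, 0.0376), glucocorticoid response (0.22, 0.00168), mitochondrially encoded (0.12, 0.0189), microglia (0.12, 0.019) and astrocyte genes (0.080, 0.00615) were higher by their medians. With an estimated correlation the adjusted p of the 13 ran from 0.578 to 0.665. The mitochondrially encoded genes turned lower without naive high 1 (adjusted p = 0.859) and the ribosomal protein genes higher without CRS low 1 (adjusted p = 0.925). In edgeR 0 genes passed (1785 at an unadjusted p below 0.05), 43 in DESeq2 and 0 in limma, and 0 with the replicate block in edgeR.

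Whether FST class went with different transcripts after stress was tested as an interaction in LHb, the high minus low difference in CRS less that in naive mice. High and low were cut at 50 s of immobility in naive and at 110 s in CRS mice, so the classes cover different ranges. Shc3 was at −3.13 ± 0.17 (adjusted p = 9.1e-06), Acvr2b at −2.24 ± 0.21 (adjusted p = 0.000729), and Hipk2 at −2.18 ± 0.21 (adjusted p = 0.000752). Pdpr was at −1.46 ± 0.14 (adjusted p = 0.000765) and Faxc at −1.49 ± 0.16 (adjusted p = 0.00245). Ghrl (−4.16 ± 0.64, adjusted p = 0.0233), Aff2 (−2.37 ± 0.34, adjusted p = 0.0154), Zkscan16 (−2.35 ± 0.40, adjusted p = 0.0396) and the channel gene Kcna1 (−1.49 ± 0.17, adjusted p = 0.00375) passed as well. In edgeR 47 genes passed, 46 lower and 1 higher, which was Pgr15l (7.77 ± 1.09, adjusted p = 0.0239), named after its values were seen. Pgr15l fell outside the naming rule, with a mean below 1 FPKM, so its log2 difference rests on low levels.

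Camera called 8 lists for the interaction, and with an estimated correlation none, with adjusted p = 0.913 or more. Immediate early genes were negative in 27 of 33 (median −0.48, adjusted p = 1.1e-05), with Fos at −1.16 and Fosb at −1.39, which did not pass alone. Thalamic markers (−0.25, adjusted p = 0.00508) and ion channels (−0.12, 0.0051) were negative by their medians, and endothelial (0.37, 1.1e-05), mitochondrially encoded (0.15, 0.00103), choroid plexus (2.31, 0.0189), leptomeningeal (0.996, 0.0198) and lysosome genes (0.076, 0.0284) positive, with leptomeningeal genes turning lower without naive low 1 (adjusted p = 0.880). Without the 4 libraries with pancreas transcripts 2 genes passed, with 1 CRS high library left, and without the 3 with the most Ttr 97.

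In vHippo, CRS libraries held more transcripts of oligodendrocytes. Mal, a myelin membrane gene, was at 72.1 ± 46.3 FPKM in CRS and 24.8 ± 4.51 in naive mice (SD, n = 3 each; log2 fold change 1.51 ± 0.42) and Tspan2 at 29.0 against 12.3 (1.21 ± 0.33), with adjusted p = 0.750. Ppp1r14a and Ugt8a were at 1.46 ± 0.37 and 1.45 ± 0.42, with the same adjusted p. All 25 myelin genes were positive (median 1.23, adjusted p = 9.8e-17 in camera; adjusted p = 0.801 with an estimated correlation), and 22 passed adjusted over the list alone, against 0 over all genes tested. The mean log2(FPKM + 1) over the list was 4.19, 4.94 and 3.33 in the CRS libraries and 3.03, 3.26 and 3.36 in the naive ones, so the difference came from CRS 1 and CRS 2. Of these CRS 2 also held skeletal muscle and skin transcripts, at 23.1 and 42.0 FPKM in sum, and CRS 1 had 2.56 and 3.91. Endothelial genes were higher (median 0.21, adjusted p = 0.000186, 7 adjusted over the list alone; adjusted p = 0.330 with an estimated correlation), with the transporter genes Slco1a4 at 8.38 ± 1.08 against 5.03 ± 0.662 FPKM (0.72 ± 0.12) and Abcb1a at 0.75 ± 0.15. The others of smallest p were Rbm3, a cold-inducible RNA-binding protein gene (0.42 ± 0.07), Gng12 (0.44 ± 0.09), Fam220a (−1.04 ± 0.17), Trp53i11 (−0.55 ± 0.10) and Spp1, which encodes osteopontin (−2.40 ± 0.45), and they did not pass (adjusted p = 0.750).

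Other lists called in vHippo as higher were astrocyte (median 0.18, adjusted p = 0.0036), microglia (0.19, 0.0123) and mitochondrially encoded genes (0.14, 0.00169). Called as lower were oxidative phosphorylation (−0.13, 1.8e-05), ribosomal protein (−0.13, 4.0e-05), pan-neuronal (−0.14, 0.0052), chaperone (−0.11, 0.0052), synaptic vesicle (−0.12, 0.00623), unfolded protein response (−0.097, 0.0382) and proteasome genes (−0.069, 0.046), the last turning higher without CRS 2 (adjusted p = 0.228). With an estimated correlation none of these was called, with adjusted p = 0.801. Over all genes in vHippo, 0 passed in edgeR (1330 at an unadjusted p below 0.05), 43 in DESeq2 and 0 in limma.

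In VTA the libraries differed widely in dopaminergic neuron transcripts. Th was at 98.0, 114 and 420 FPKM in CRS and at 161, 12.4 and 75.9 in naive libraries. Of dopaminergic markers 20 of 21 were positive (median 0.91, adjusted p = 4.6e-07; adjusted p = 0.612 with an estimated correlation), with Calb1 at 0.91 ± 0.41 and Chrna6 at 1.35 ± 0.77. Immediate early genes were negative in 31 of 33 (median −0.72, adjusted p = 1.5e-08; adjusted p = 0.612 with an estimated correlation), with Jun at −0.49 ± 0.17 and Apold1 at −1.74. Fos was at 15.8 FPKM in naive 2, where Hba-a1, a haemoglobin gene, was at 118 FPKM and at 7.29 or less in the others. Pmch, of the hypothalamus, was at 136 FPKM in naive 2 and 129 in CRS 1. The metallothionein gene Mt2 was at 55.8 ± 2.44 against 34.4 ± 2.32 FPKM (SD, n = 3 each; log2 fold change 0.66 ± 0.11) and higher in 3 of 3 CRS libraries, but did not pass (adjusted p = 1). Neither did Tceal5 (0.60 ± 0.14), Rgs5 (−0.56 ± 0.13), Sned1 (−0.47 ± 0.13) and Ndor1, whose 2 overlapping IDs were at 3.98 ± 0.80 and −0.48 ± 0.12. Camera also called ribosomal protein genes (0.13, 2.0e-09), oxidative phosphorylation (0.093, 0.00025), proteasome (0.070, 0.0106) and astrocyte genes (0.094, 0.0257) as higher. It called endothelial (−0.24, 4.0e-09), mitochondrially encoded (−0.40, 1.1e-06), interferon response (−0.32, 7.9e-06), red blood cell (−2.03, 0.00306), myelin (−0.21, 0.0257) and leptomeningeal genes (−0.23, 0.03) as lower, and myelin genes turned higher without naive 3 (adjusted p = 0.0797). With an estimated correlation none of the 12 was called, with adjusted p = 0.612 or more. In edgeR 0 genes passed in VTA (325 at an unadjusted p below 0.05), 8 in DESeq2 and 0 in limma.

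In NAc, striatal projection neuron markers were higher in CRS mice. The list was positive in 22 of 23 genes (median 0.48, adjusted p = 9.9e-11; adjusted p = 0.713 with an estimated correlation). Drd1, the D1 dopamine receptor, was at 50.7 against 33.6 FPKM (log2 fold change 0.63 ± 0.25), Gpr6 at 0.85 ± 0.29 and Drd2 at 0.58. Circadian clock genes were positive in 17 of 19 (median 0.16, adjusted p = 9.1e-06; adjusted p = 0.713 with an estimated correlation), with Per2 at 0.70 ± 0.24 and Cry1 at 0.54. Endothelial genes were lower (median −0.17, adjusted p = 0.000861; adjusted p = 0.420 with an estimated correlation). Camera called cortical projection neuron markers as higher (adjusted p = 0.0242; adjusted p = 0.713 with an estimated correlation) while their median was −0.092 and their mean −0.13, and Slc17a7 was at 180, 0.506 and 3.54 FPKM in naive and 67.4, 63.1 and 1.45 in CRS libraries. Cpne1 (0.53 ± 0.14), Itgbl1 (0.57 ± 0.15), Arhgdib (0.81 ± 0.22), Lrch4 (−1.24 ± 0.30), Hnrnpa3, which has many pseudogenes (−3.06 ± 0.77), and the synapse organiser Cbln1 (−1.35 ± 0.34) had the smallest p and did not pass (adjusted p = 1). Over all genes in NAc, 0 passed in edgeR (442 at an unadjusted p below 0.05), 1 in DESeq2 and 1 in limma, and 0 in edgeR with the replicate block.

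In mPFC, genes of energy metabolism and of protein turnover were higher in CRS mice by their medians. None of the 6 lists called here was called with an estimated correlation (adjusted p = 0.971 or more). Positive were 60 of 61 genes of oxidative phosphorylation (median 0.27, adjusted p = 1.6e-07), 30 of 31 of the proteasome (0.25, 7.4e-05) and 63 of 66 ribosomal protein genes (0.19, 0.00252), with Uqcrb at 0.71 and Psma5 at 0.45. The mean log2(FPKM + 1) of oxidative phosphorylation was 5.35, 4.63 and 4.61 in CRS and 4.40, 4.64 and 4.80 in naive libraries, so CRS 1 stood apart. Over genes higher in the other LHb groups than in naive low FST mice, CRS 1 was also lowest of the 30 libraries, at a mean log2 deviation of −0.792. Without CRS 1 the direction of all 3 lists in camera turned to lower, with adjusted p = 0.603, 0.790 and 0.00966, and the ribosomal protein genes did so without naive 1 as well (adjusted p = 0.788). Neuropeptide genes were higher (0.29, 0.0475), and immediate early (−0.30, 0.00252, with Nr4a3 at −0.67) and leptomeningeal genes (−1.64, 0.0179) lower, the last turning higher without naive 3 (adjusted p = 0.0398). Ttr was at 1.78 ± 0.230 against 0.240 ± 0.134 FPKM (SD, n = 3 each; log2 fold change 2.86 ± 0.51). The muscle genes Atp2a1 and Ckm were at −5.03 ± 0.86 and −8.34 ± 1.77, with Ckm at 2.02, 7.01 and 0.091 FPKM in the naive libraries. Rbm3 (0.80 ± 0.22), Atp6ap1l (1.18 ± 0.26) and Tpm2 (−2.54 ± 0.60) were the others of smallest p, and none of these passed (adjusted p = 1). In edgeR 0 genes passed in mPFC (314 at an unadjusted p below 0.05), 24 in DESeq2 and 0 in limma.

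In LH, CRS libraries held fewer transcripts of oligodendrocytes and of thalamic neurons. Mobp, a myelin protein gene, was at 125 ± 11.8 FPKM in CRS and 332 ± 162 in naive mice (SD, n = 3 each; log2 fold change −1.49 ± 0.35). Cldn11, of myelin tight junctions, was at −1.39 ± 0.31 and Enpp2 at −1.14 ± 0.23, each with adjusted p = 0.424 or more. All 25 myelin genes were negative (median −1.2006, adjusted p = 1.1e-21; adjusted p = 0.475 with an estimated correlation), and 24 passed adjusted over the list alone, against 0 over all genes tested. Thalamic neuron markers were lower (median −0.96, adjusted p = 0.000207, 12 adjusted over the list alone; adjusted p = 0.475 with an estimated correlation), with Ramp3 at −4.38 ± 1.11 and Prkcd at −3.32 ± 0.88. Their mean log2(FPKM + 1) was 3.36, 3.33 and 2.47 in naive and 2.52, 2.48 and 2.41 in CRS libraries. For myelin genes it was 5.87, 5.92 and 4.89 against 4.80, 4.71 and 4.36, so naive 1 and naive 2 stood apart in both. Of these naive 2 also held skeletal muscle and skin transcripts, at 92.5 and 49.6 FPKM in sum, and naive 1 had 2.68 and 2.58. Ependymal genes of motile cilia had some of the smallest p. Foxj1, their master transcription factor, was at 8.13 ± 1.65 against 3.24 ± 0.563 FPKM (1.25 ± 0.20), Odf3b at 2.39 ± 0.39 and Catip at 2.48 ± 0.41. Ttr was at 1.14 against 17.3 ± 3.998 FPKM (−4.02 ± 0.77), S100a16 at −0.72 ± 0.13 and Adamtsl4 at −1.62 ± 0.31, and none of them passed (adjusted p = 0.424).

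**Figure D2:**
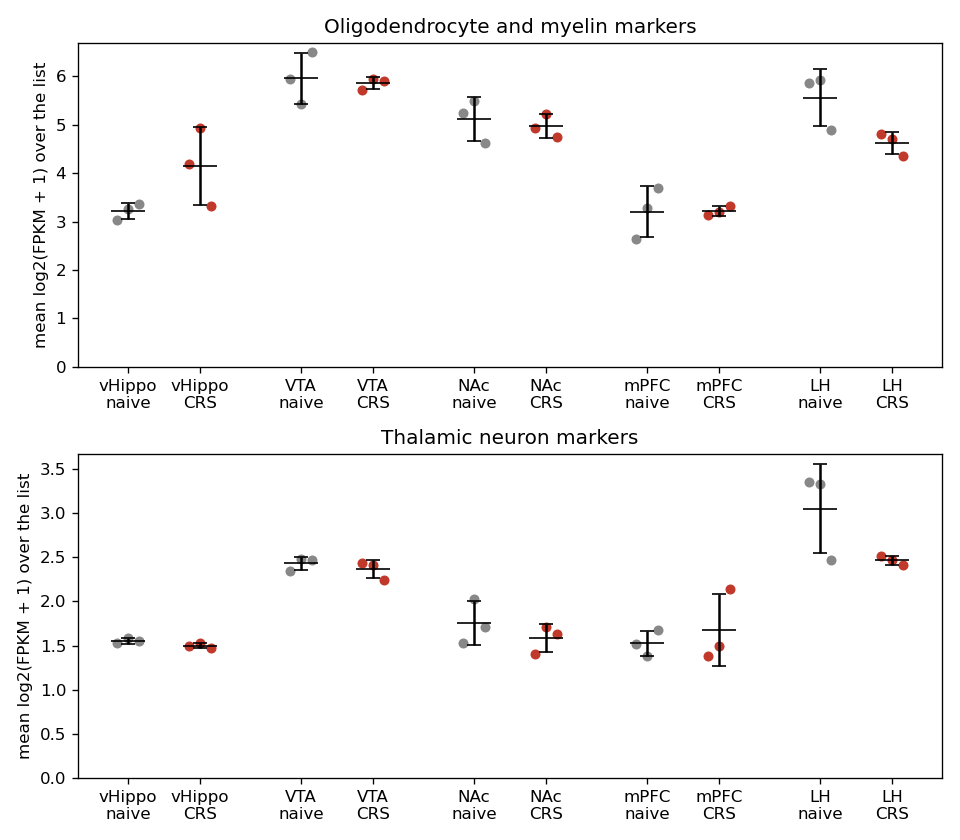
Mean log2(FPKM + 1) over oligodendrocyte and myelin markers and over thalamic neuron markers in each library of 5 regions (points; naive grey, CRS red), with the mean and SD of each group of 3 (black). In LH the naive libraries sat at 5.87, 5.92 and 4.89 for myelin, and in vHippo the CRS libraries at 4.19, 4.94 and 3.33.

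Camera called 13 lists in LH, and with an estimated correlation none, with adjusted p = 0.475 or more. All 61 genes of oxidative phosphorylation (median −0.25, adjusted p = 4.6e-12) and all 20 microglia genes (−0.37, 2.9e-07) were negative, with Cox5a at −0.58 and the complement gene C1qb at −0.60. Leptomeningeal (−0.73, 0.000112), mitochondrially encoded (−0.28, 0.000233), pan-neuronal (−0.16, 0.0199), oligodendrocyte precursor (−0.10, 0.00321) and lysosome genes (−0.075, 0.0208) were lower by their medians. Hypothalamic neuron markers were positive in 19 of 23 (0.56, 9.6e-05), with Hdc, of histamine synthesis, at 3.39 ± 1.17, and choroid plexus and ependymal (0.76, 0.00321), dopaminergic (0.60, 0.0199) and neuropeptide genes (0.59, 0.0129) were higher. Over all genes in LH, 0 passed in edgeR (1896 at an unadjusted p below 0.05), 336 in DESeq2 and 0 in limma. Without naive 3, whose myelin and thalamic levels lay near those of the CRS libraries, 760 genes passed, 363 higher and 397 lower.

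Of the 16 focus genes 0 passed in any of the 5 regions, over all genes tested or adjusted over the list alone, and 1 each in vHippo, NAc and LH had an unadjusted p below 0.05. The autophagy lists were not called, with adjusted p = 0.811 and 0.832 in vHippo, 0.982 for both in VTA, 0.590 and 0.816 in NAc, 0.852 for both in mPFC, and 0.0979 and 0.268 in LH. Whether the CRS effect differed between the 5 regions was tested gene by gene. Mal, at 1.497 in vHippo and −1.28 in LH, Mobp, at 1.75 and −1.49, and the myelin genes Tspan2, Ugt8a and Ermn were among those of smallest p, with Cyp2j12, Trim59 and Gatm. None passed: 0 genes in edgeR, with 1074 at an unadjusted p below 0.05.

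Simulated genes in LHb data were recovered by edgeR at folds of 1.5, 2, 3 and 4 in 20, 31, 37 and 36 of 50 for CRS and naive mice, and 9, 19, 26 and 26 for naive FST classes. They were 8, 21, 29 and 35 for CRS high and naive low, and 10, 19, 28 and 29 for CRS FST classes. For CRS low and naive high they were 3, 15, 31 and 33, and for the interaction 3, 17, 20 and 24. The same folds were recovered in 3, 25, 31 and 35 in vHippo, 0, 2, 19 and 29 in VTA and 0, 8, 25 and 33 in NAc. They were 0, 1, 17 and 22 in mPFC, 0, 15, 33 and 32 in LH, and 0, 2, 12 and 26 for the test between regions. For the test between regions the changes were planted in mPFC CRS libraries alone, and for the LHb interaction in CRS high libraries alone. Changes in other groups, or opposite changes in different regions, were not simulated for these tests. At 1.5-fold, where edgeR recovered 0 genes, DESeq2 recovered 6 in VTA, 1 in NAc, 0 in mPFC and 7 in LH. False calls on simulated data were 2 to 9 in edgeR within LHb and within single regions, 1 in edgeR between regions, and 38 to 60 in DESeq2.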

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

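All tests of explanations, all splits and the contrast of CRS effects between LH and vHippo in this part were chosen after the results were seen. The interaction of stress and FST class in LHb was planned.

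In LHb the FST classes were cut at 50 s of immobility in naive and at 110 s in CRS mice. The interaction thus cannot show that an effect of immobility depends on stress. By its test, the high minus low difference was not the same in CRS and naive mice for 47 genes. Named among them were Ghrl (log2 −4.16), Shc3 (−3.13), Aff2 (−2.37), Zkscan16 (−2.35), Acvr2b (−2.24), Hipk2 (−2.18), Faxc (−1.49) and Pdpr (−1.46), all lower in the naive low FST libraries than in the other LHb groups. Over 100 splits of the 12 libraries, 5 gave as many genes, the real one included, with up to 124 in another split, so chance cannot be excluded for that count. These splits were drawn freely and do not allow for any pairing by replicate number.

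The 3 naive low FST libraries differed in 715 genes from naive high and in 854 from CRS high FST mice, and Shc3 was at 0.787 to 0.861 FPKM in them and 5.73 to 7.55 in the other 9 LHb libraries. Over the 918 genes higher in the other groups, chosen by that contrast, CRS low 1 lay between, at a mean log2 deviation of −0.0397. The naive low libraries were at −0.979 to −0.804 and the remaining LHb libraries at 0.264 to 0.481. Genes higher in the other groups were long, with a median transcript of 6375 nt against 2722 nt in genes that did not pass, but 521 of the 715 stayed past the threshold with an offset for length and GC content, and the gene length implied by counts and FPKM had a median ratio of 0.971, which argues against a length or GC trend and against differing gene models as the whole cause. A difference in library or RNA quality stays open and may account for the pattern: the 3 libraries had the highest mitochondrial shares in LHb (7.13% to 7.43%, against 5.25% to 6.96%), and 2 of them the fewest genes detected (25992 and 26486). Over the 885 genes measured in the other regions of those chosen because they were lower in the 3 libraries, mPFC CRS 1 was at −0.792 in mean log2 deviation, where the lowest of 1000 matched gene sets was at −0.251, and of the 30 libraries of other regions 8 lay below and 11 above all matched sets. Low immobility in naive mice, the biological explanation that the design gives, is confounded with those 3 libraries and stays open as untested.

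Pancreas transcripts stood in 4 of the 12 LHb libraries, naive high 3, CRS high 2, CRS high 3 and CRS low 2, at 358 to 472 FPKM in sum and 0.0374% to 0.0672% of counts. At least 8 of the 12 listed transcripts were at 1 FPKM or more in each of the 4, which is consistent with RNA of another tissue. A single source shared by all 4 is argued against by insulin: the ratio of Ins2 to the digestive enzyme gene Ctrb1 was 1.06 in naive high 3 and 0 in the other 3. Of the pancreas genes tested, 0 of 11 passed in the 6 planned LHb comparisons (smallest adjusted p = 0.0830), so the genes named there were others. No biological explanation was tested, and the step at which the RNA came in stays open.

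Myelin transcripts moved apart in vHippo and LH. The CRS effect in LH less that in vHippo was tested for that reason, so its values are no separate test of the difference. In this contrast 25 of 25 myelin genes passed adjusted over the list alone (median −2.48). Camera gave the list an adjusted p of 2.0e-44, and of 0.0826 with an estimated correlation. Over all genes 0 passed in edgeR and 1671 had an unadjusted p below 0.05. In LH tissue of a neighbouring region could be the source, since 12 thalamic neuron markers were lower with CRS adjusted over the list alone. In vHippo 0 thalamic markers passed, which decides nothing, as other neighbours have other markers. A lower share of neurons in vHippo that raised all other cell types alike is argued against as the whole cause. The upper quartile of 64 astrocyte, microglia and vessel genes was 0.362 where the lower quartile of myelin genes was 1.13. A lower share of neurons as a part of it stays open, since camera called astrocyte, microglia and endothelial lists higher in vHippo and pan-neuronal genes lower. An effect of CRS on oligodendrocytes, the biological explanation, stays open as untested, as does what went with the muscle and skin transcripts in vHippo CRS 2 and LH naive 2, each among the libraries with the most myelin transcripts in its region.

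For CRS against naive LHb, 1 of 100 splits gave as many genes as the real 273, which was the real split, the lowest share that 100 splits can give. That argues against chance for the grouping of the 12 libraries as a whole. The splits were drawn freely, though, and do not allow for any pairing by replicate number. Chance is not excluded for CRS given the naive low FST group: the 3 other splits that kept those libraries in 1 group gave a median of 158 and up to 215, the highest of all others. Such splits, 4 in all, are too few for a share under 0.05. For the other 3 LHb groups against naive low FST, 2 of 100 gave as many as 1053, and the other of the 2 gave 1321, which points to a further structure of the samples. That contrast was chosen because the group stood apart, so its splits decide nothing about chance. In the test between regions the real count was 0, so all 40 of 40 splits gave as many, with up to 16, which decides nothing. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. Between naive FST classes the real split gave 715 and the highest other 0, and between CRS high and naive low 854 and 1. For CRS low against naive high, vHippo, VTA, mPFC and LH the real split gave 0 and the highest other 1; a real count of 0 makes all 10 of 10 at least as large and decides nothing. CRS high against CRS low gave 0, and 39 in the split that set the 3 CRS libraries with pancreas transcripts apart, which points to a structure of the samples. The opposite side held CRS high 1 and CRS low 1, with choroid plexus RNA, so the split cannot tell pancreas from choroid plexus RNA as its source. NAc gave 0, and 28 in the split that put naive 1, CRS 1 and CRS 2 together, the 3 libraries with the most Slc17a7, again a structure of the samples.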

How the results depend on the processing

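Fits without the naive low FST, choroid plexus or pancreas libraries, without ribosomal and mitochondrial genes, and with an offset for transcript length and GC content were tests chosen after the data were seen, as was every alternative for the test between regions.

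In LHb the counts of 273 (CRS and naive), 715 (naive FST classes), 854 (CRS high and naive low) and 47 (interaction) stayed within 1.5 times with RLE factors (292, 708, 868, 51), without a filter (202, 537, 637, 34), with the replicate block (376, 1041, 942, 67) and without ribosomal and mitochondrial genes (285, 735, 859, 60). The balance moved more than the totals between naive FST classes, where 625 were higher and 90 lower: the lower genes were 275 of 1041 with the replicate block, 407 of 1673 in DESeq2, 125 of 489 in limma on log2(FPKM + 1), 168 of 681 with the length and GC offset and 41 of 537 without a filter. DESeq2 called 772, of which 273 were shared, 1673, 1591 and 325, and 2 and 43 where edgeR called 0 (CRS FST classes; CRS low and naive high). It called 43 in vHippo, 8 in VTA, 1 in NAc, 24 in mPFC and 336 in LH, where edgeR called 0. On simulated data it made more false calls, but the cause of these differences was not tested. In limma the interaction had 19 genes on log2(FPKM + 1), 22 with 0.1 added and 19 after median-ratio scaling, and NAc had 1 on log2(FPKM + 1) and 1 after median-ratio scaling, and the cause was not tested. A filter of at least 5 FPKM, which leaves fewer genes, gave 441 between naive FST classes, 529 for CRS high and naive low and 18 for the interaction. With the replicate block mPFC had 1 gene and LH 1, for which the cause was not tested, and the other regions 0. A fit of all 30 libraries gave 0 in each region.

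Without the naive low FST libraries, thus fewer samples, CRS and naive LHb differed in 0 genes, and the log2 fold changes of Ghrl (−0.0882), Slc9a7 (−0.0752), Klhl11 (−0.191), Oprm1 (−0.0586), Shc3 (−0.00342) and Acvr2b (−0.0135) turned negative, with adjusted p from 0.921 to 0.995. Without the 4 libraries with pancreas transcripts, again fewer samples, 2 (Shc3 and Hipk2), 138, 57 and 2 genes passed in the 4 comparisons with calls, of which 2, 136, 55 and 1 were shared. That leaves 1 CRS high library, assumed to vary like the other groups, so the lower counts do not show a dependence on the pancreas RNA. Without the 3 choroid plexus libraries the interaction had 97. The offset for length and GC content left 147 for CRS and naive LHb, and ended the calls of Klhl11, Oprm1, Ahsa2, Clk4 and Amd1. For the last 2 settings the cause was not tested.

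Leaving out 1 library gave 134 to 474 genes for CRS and naive LHb, 330 to 650 between naive FST classes, 422 to 708 for CRS high and naive low, 21 to 218 for the interaction, 0 to 11 for CRS low and naive high, 0 to 1 for CRS FST classes, 0 to 0 in vHippo and VTA, 0 to 1 in NAc, 0 to 4 in mPFC, 0 to 760 in LH and 0 to 2 in the test between regions. For CRS and naive LHb the count moved by over 1.5 times without naive low 3 (142), naive high 2 (166), naive high 3 (136), CRS high 1 (167), CRS high 2 (143), CRS low 1 (474), CRS low 2 (134) and CRS low 3 (165). Between naive FST classes it did so without naive low 1 (383), naive low 3 (330), naive high 2 (414) and naive high 3 (448), and for CRS high and naive low without naive low 1 (513), naive low 3 (424) and CRS high 2 (422). For the interaction these were naive low 3 (27), naive high 1 (27), naive high 2 (30), CRS high 1 (21), CRS high 3 (22), CRS low 1 (218), CRS low 2 (25) and CRS low 3 (23). Counts of 0 became 11 without naive high 1 (CRS low and naive high), 1 without CRS high 3 or CRS low 3 (CRS FST classes), 1 without naive 1 or CRS 2 in NAc, 4 without naive 3 in mPFC, and in LH 1 without naive 2, 760 without naive 3 and 1 without CRS 3. In the test between regions 2 passed without LH naive 3. Fewer samples can lower a count, but whether that alone gave the lower counts was not tested. For the counts that grew the cause was not tested either.

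Of named genes past the threshold, 1492 of 1968 tests under an alternative kept direction and call, 470 lost the call and 6 reversed, and of those not past it, 11473 of 11736 stayed so and 263 passed. Shc3, Hipk2, Acvr2b, Pdpr and Faxc kept their call in LHb whichever single library was left out, while Klhl11, Oprm1 and Amd1 lost theirs for CRS and naive in several such fits.

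Of 102 called lists the estimated correlation kept 0, fry 2 and the replicate block 100, and leaving out 1 library kept 567 of 708, weakened 131 and reversed 10. Adjusted p in camera over those fits is given here for each list that reversed in one. Leptomeningeal genes in the interaction ran from 0.00014 to 0.880, reversed without naive low 1 (0.880). For CRS low and naive high, mitochondrially encoded genes ran from 8.03e-09 to 0.859, reversed without naive high 1 (0.859), and ribosomal protein genes from 5.00e-07 to 0.925, reversed without CRS low 1 (0.925). Proteasome genes in vHippo ran from 0.000942 to 0.490, reversed without CRS 2 (0.228), and myelin genes in VTA from 3.76e-15 to 0.753, reversed without naive 3 (0.0797). In mPFC, 3 lists reversed without CRS 1: oxidative phosphorylation (3.71e-14 to 0.603; 0.603), proteasome (8.44e-13 to 0.790; 0.790) and ribosomal protein genes (3.01e-09 to 0.788; 0.00966). The last also reversed without naive 1 (0.788), and leptomeningeal genes (4.52e-07 to 0.786) without naive 3 (0.0398). The cause was not tested.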

Other observations

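The contrasts of LHb groups with naive low FST mice in this part, and the lists of transcripts of other tissues, were tests chosen after the results were seen.

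Immediate early genes of LHb were higher in CRS low than in naive low FST mice. Fosb, a subunit of the AP-1 transcription factor, was at 4.24 ± 1.86 against 1.46 ± 0.258 FPKM (SD, n = 3 each; log2 fold change 1.54 ± 0.32, adjusted p = 0.0236) and Atf3, a stress-induced transcription factor, at 1.97 ± 0.41 (adjusted p = 0.0251). The list had a median of 0.47 (adjusted p = 8.6e-07; adjusted p = 0.974 with an estimated correlation), and 10 genes passed adjusted over the list alone. Kcna1 rose by 1.54 ± 0.13 (adjusted p = 8.5e-05), with the channel genes Kcnn3 and Kcna2 at 0.61 and 0.60, and Atg2b, Wdfy3 and Epg5 by 0.79, 0.75 and 0.67 (adjusted p from 0.00046 to 0.00755). In edgeR 510 genes passed, 492 higher and 18 lower. Against the other 3 groups together 1053 passed, 918 higher and 135 lower, among them Atf3 (1.62), Fosb (1.24), Apold1 (1.18) and the NMDA receptor gene Grin2b, at 2.64 ± 0.390 against 1.73 ± 0.400 FPKM (0.63 ± 0.16, adjusted p = 0.0410), the only one of the 16 focus genes to pass there.

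Naive high and CRS high FST mice shared the naive low group as control, which alone makes the effects alike. Across genes, which are not independent replicates, the effects had a Pearson r of 0.691, against 0.494 in simulated data with a shared control and no shared effect. The simulation drew libraries independently and does not allow for any pairing by replicate number. It also gave the naive low libraries no shift of their own. Such a shift, from library quality or another source, would raise r with no effect shared by naive high and CRS high mice. The higher r thus does not show a shared effect. In both comparisons 560 genes were higher, a number with no value under a shared control alone to set it against. CRS effects of different regions had an r across genes from −0.179 (LHb and mPFC) to 0.180 (VTA and mPFC) over 15 pairs, and of −0.320 for vHippo and LH over the more abundant genes.

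Transcripts of other tissues stood in single libraries. Skeletal muscle transcripts summed to 165 FPKM in VTA naive 3, 92.5 in LH naive 2, 74.6 and 22.9 in mPFC naive 2 and naive 1, 23.1 in vHippo CRS 2 and 19.8 in NAc CRS 1, and skin transcripts to 35.0 to 49.6 in the same 6 libraries, against 5.66 and 6.06 or less in the rest of the 5 regions. Olfactory bulb transcripts summed to 201 FPKM in mPFC CRS 3, where Cdhr1 was at 87.3, and to 7.26 or less in the other libraries of the 5 regions. Pineal transcripts summed to 8.13 FPKM in LHb CRS high 1 and 6.79 in CRS low 2.

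Replicate numbers of the labels were checked for pairing, which the labels do not state. Over 18 pairs of LHb libraries the correlation across genes of deviations from the group mean ran from −0.0101 to 0.487, and over 15 pairs of the other regions from −0.629 to 0.440, with 15 and 8 above 0.1. The highest in LHb, from 0.442 to 0.487, were those among naive low 1, CRS high 1 and CRS low 1. These libraries held choroid plexus RNA, so their values cannot tell pairing from that RNA. In 15 of the 18 LHb pairs and 8 of the 15 others, the same number gave the highest correlation among the replicates of the second group. Among pairs with naive high libraries, which held little Ttr, only CRS high 2 with naive high 2 (−0.0101) had another number highest. Pairing is thus not excluded, and the main fits did not allow for it. All 3 pairs of NAc and all 3 of CRS high with naive low, CRS low with naive high and CRS low with naive low were above 0.1.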
